A study of Pseudomonas aeruginosa with 2 samples.

How the data were processed

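Gene expression was measured in biofilm cells of Pseudomonas aeruginosa PAO1, a widely used laboratory strain, with a GeneChip P. aeruginosa Genome array. Per the labels' protocols, the cultures grew in LB medium with glass wool (10 g) as the surface for attachment, for 7 h at 37°C with shaking at 100 rpm. RNA was purified on a column with DNase digestion, and 300 ng per sample was amplified, converted to cDNA with random primers, fragmented and labelled with biotin. There were 2 arrays, 1 of a control culture and 1 of a culture that received spent medium (supernatant) of Streptomyces strain 230 at 1%. Streptomyces are soil bacteria that secrete many small molecules and enzymes.

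The deposited values are signal intensities on a linear scale, 1 per probe set (the group of short probes that measures a transcript). The authors made them with MAS5, per the submitters' processing notes, with no version stated. MAS5 is Affymetrix's summary of perfect-match and mismatch probes, which scales each array by a single factor. The mean signal without the lowest and highest 2% of the 5896 probe sets was 501 on each array, so the deposited intensities were scaled to the same target. The scaling factors, the detection calls and the scanner images were not used here. Signals are in arbitrary units, and a level of a probe set was never set against that of another probe set as an abundance.

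Of the 5896 probe sets, 396 had no gene number in GEO's platform annotation that matched a PAO1 gene. Probe sets with several genes were not counted. The other 5500 matched a locus tag of the PAO1 assembly ASM676v1 by gene number, and symbols are those of that assembly. Its coordinates are not printed because the annotation names no build. The 396 other probe sets were summarised separately. They were 199 intergenic, 138 for other strains, tRNA or rRNA, 45 with a PAO1 locus tag but no match, and 14 array controls. Among the gene probe sets, 20 carry a suffix for probes shared with other sequences.

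Each signal was raised to a floor of 108, the 20th percentile of the gene probe sets over both arrays, and the log2 ratio of supernatant over control was taken. 883 genes lay at the floor on both arrays and have a ratio of exactly 0. With 1 array per group there is no replicate error, no test between the conditions and no p-value, so every difference describes these 2 arrays. Differences are described by size, with a ratio of at least 2 in either direction as the threshold. The number of arrays sets the precision.

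Before the data were examined, 40 lists of genes were fixed by locus tag. They held 673 entries, of which 658 were measured. The median log2 ratio of each list was placed among those of 10000 random lists of the same size, matched on the decile of mean log2 signal, and given as a percentile. Percentiles at or above 97.5 or at or below 2.5 were counted. If the genes of a list were independent, about 2 of 40 lists would fall outside these bounds with no effect at all. Many lists hold operons, whose genes vary together, so more lists than that could fall outside. The percentile is a description and not a test, because genes of an operon are not independent. Also fixed beforehand was the rule for the genes named: the 15 highest and 15 lowest ratios among genes whose brighter signal was at or above the median of 268, and in each list up to 4 members above the floor with the largest ratio in the direction of the list, plus members that reached 2-fold the other way. rpoD and the other housekeeping genes were also fixed to be given on both arrays. Genes named outside this rule are marked as chosen after their values were seen, or belong to a test that was set before. A correlation between the log2 ratios of genes with consecutive locus tags was compared with 1000 shuffles of the gene order.

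On simulated arrays made from the mean signals of the 5500 genes with added noise, the 2-fold threshold recovered 72% of 50 genes changed 2.5-fold, 92% of 50 genes changed 4-fold, 80% of 50 changed 8-fold and 0% of 50 changed 1.5-fold. None of the unchanged simulated genes (0%) passed it, but the noise was assumed, not measured. At middle and high signal it was smaller than the observed spread of ratios (SD 0.41 in the 6th decile and 0.35 in the 10th). That spread also holds any real differences, so the simulated rates may be optimistic. Of 100 simulated lists of 12 unshifted genes, 4% fell outside the percentile bounds, and all of 20 lists (100%) shifted by 0.5 on the log2 scale lay above the upper bound. The simulated noise was independent from gene to gene, so these rates do not cover lists of operon genes.

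The alternatives tried were a median log2 ratio set to 0, quantile normalization, loess of the ratio on mean signal with a span of 0.3, no floor, a floor at the 40th percentile, fold thresholds of 1.5 and 3, list means in place of medians, and random lists without matching. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and R 4.3.3 with limma 3.58.1 for loess.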

Results

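The data were 2 expression arrays of PAO1 biofilms that had formed on glass wool over 7 h, 1 of an untreated control culture and 1 of a culture with 1% Streptomyces 230 supernatant. The series looked for Streptomyces products that reduce biofilm formation, and the single comparison shows how transcript levels of the attached cells differed when the supernatant was present. The signals summed to 4022644 on the control array and 3763358 on the supernatant array, with gene medians of 272 and 263. The log2 signals of the 5500 genes correlated across genes with Pearson's r = 0.97, and the signals with Spearman's rho = 0.96; genes are not independent replicates. No value below has a replicate error, and no difference between the conditions could be tested.

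Genes of iron scavenging, glycerol use and phenazine synthesis were higher on the supernatant array, and a transporter of the glucose uptake group was lower. Of the 5500 genes, 53 (0.964%) were at least 2-fold higher and 23 (0.418%) at least 2-fold lower. The lists fixed beforehand held 33 of the 53 higher genes and 4 of the 23 lower genes, although they covered 657 of the 5500 genes. For 7 of the higher genes the control signal was at the floor, and for 2 of the lower genes the supernatant signal was, so these ratios depend on the floor. The SD of the log2 ratio over all genes was 0.36, with quartiles of -0.22 and 0.14. Among array controls above the floor, the 3 Bacillus subtilis probe sets for dapB, pheB and thrC had log2 ratios of -0.32, -0.27 and 0.00 (-0.0036 before rounding).

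**Figure D1:**
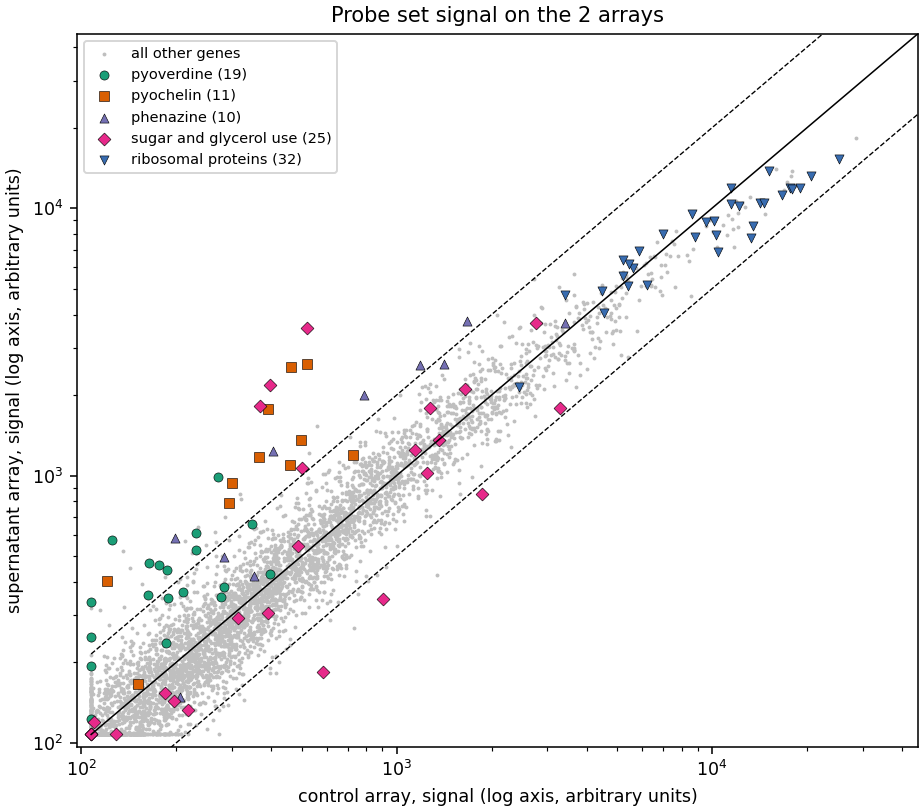
Signal of each of the 5500 genes on the control array (x) and the supernatant array (y), both log axes in arbitrary units, with values below 108 raised to that floor. The solid line marks equal signal and the dashed lines a 2-fold difference. Pyoverdine, pyochelin and phenazine genes lie on or above the upper dashed line in 10, 9 and 5 cases, and the brightest ribosomal protein genes lie below the solid line.

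Synthesis and uptake genes of both siderophores, the secreted iron carriers of the species, were higher with the supernatant. All 11 measured pyochelin genes had ratios above 1, and 9 of them were at least 2-fold higher, with a median log2 ratio of 1.64 (SD 0.69 over genes), or 3.12-fold. The largest ratios were those of pchB, 5.49-fold higher (462 to 2538), pchC, 5.03-fold higher (520 to 2614), and pchD, 4.52-fold higher (392 to 1773). These genes belong to the operon that makes salicylate and begins pyochelin assembly. They were followed by pchF at 3.34-fold, pchA at 3.22-fold and pchE at 3.12-fold, while pchR, the regulator of the operon, had a ratio of 1.09 and was chosen after its value was seen.

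All 19 pyoverdine genes were above a ratio of 1 as well, and 10 of them were at least 2-fold higher, with a median log2 ratio of 1.13 (SD 0.58 over genes). The peptide synthetase gene pvdL was 4.59-fold higher (125 to 575) and pvdA, which makes hydroxyornithine for the peptide, 3.64-fold higher (271 to 986). The gene fpvA, the outer membrane receptor of ferripyoverdine, was 2.88-fold higher, and PA2393 was 3.14-fold higher with its control signal of 85.3 raised to the floor. PA2411, which lies in the same region but outside the fixed list, was 3.24-fold higher. The sigma factor gene pvdS had a ratio of 1.27, a value looked up afterwards. Both siderophore lists lay at percentile 100 of matched random lists under each of the 6 settings of scaling and floor. With a floor at the 40th percentile the pyoverdine median log2 ratio was 0.81, under 2-fold.

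Other iron genes were uneven. Of the 17 measured genes for haem, ferrous iron and xenosiderophore uptake and iron-controlled stress enzymes, 3 were at least 2-fold higher: PA4469 at 3.85-fold, the haem receptor gene phuR at 3.17-fold and sodM, the manganese superoxide dismutase gene, at 3.05-fold over a control signal at the floor. The ferric citrate receptor gene fecA had a log2 ratio of -0.89 with its supernatant signal at the floor, and fiuA, PA0472 and tonB1 had -0.29, -0.33 and -0.22. The list median was 0.00 (percentile 63.0) while its mean was 0.24 (percentile 99.96). Of the 17 genes 6 were above 0, 6 were below and 5 were at the floor on both arrays. Without a floor the median was 0.14 (percentile 94.9).

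**Figure D2:**
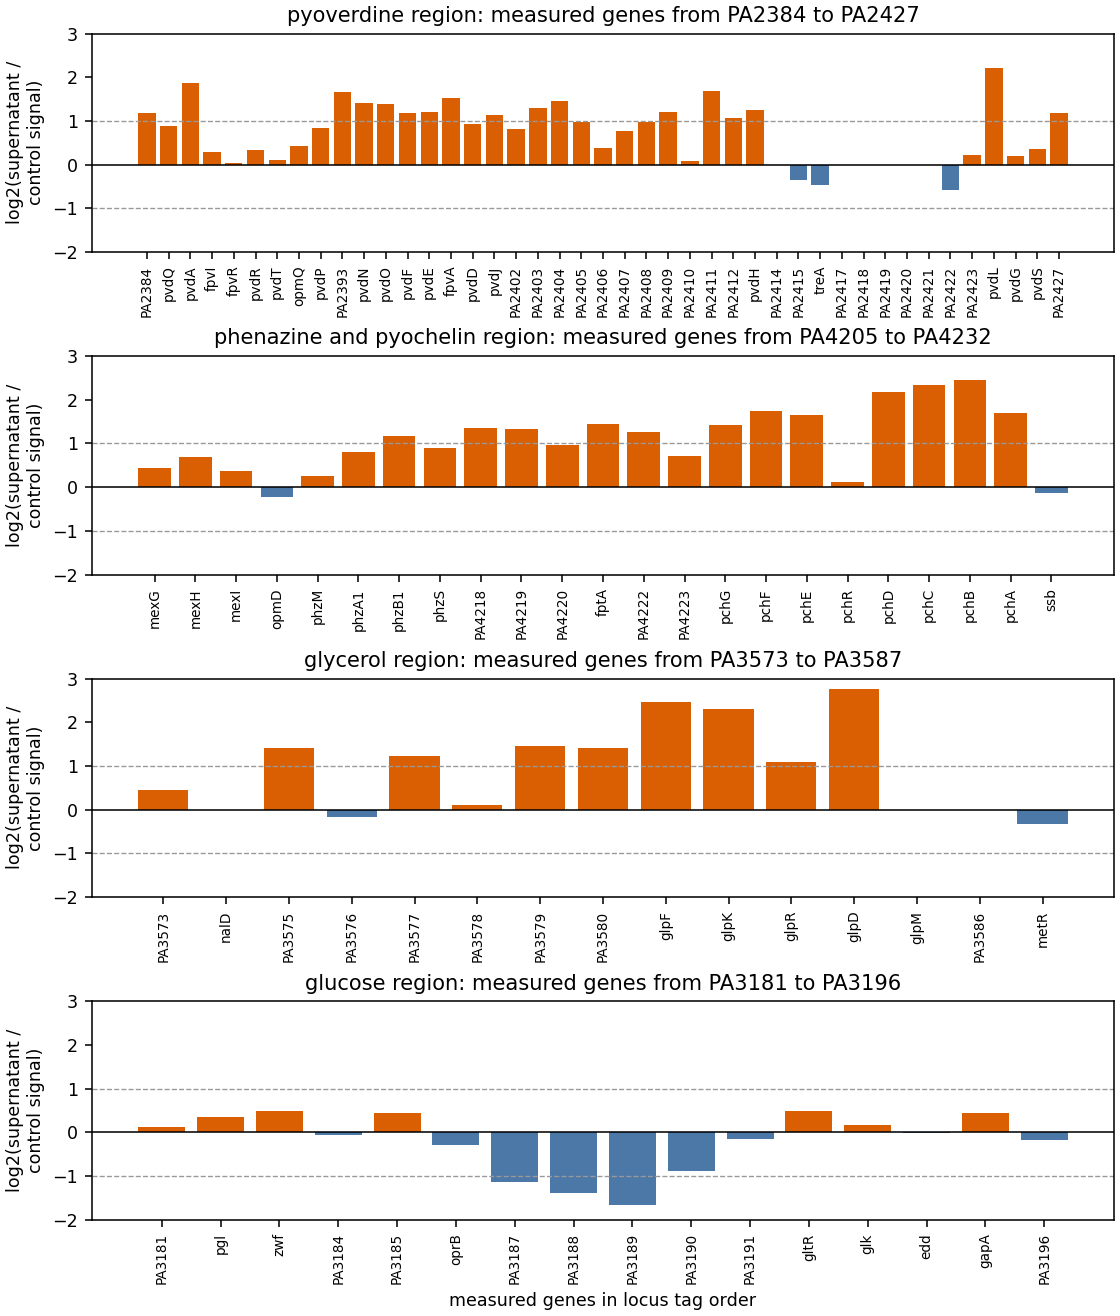
Log2 ratio of supernatant over control signal (y) for each measured gene in locus tag order (x) in 4 regions, with dashed lines at a 2-fold difference; bars are single values without error. The pyoverdine genes, the pyochelin genes and glpF, glpK, glpR and glpD are above 0, and PA3187 to PA3190 are below 0.

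Phenazine genes, which make the redox-active pigment pyocyanin and related compounds, were higher in 9 of 10 measured cases, and 5 were at least 2-fold higher (median log2 ratio 1.01, percentile 100). The probe sets of phzF2, phzD2 and phzE2 were 3.05-fold, 2.94-fold and 2.54-fold higher, and that of phzB1 was 2.26-fold higher (1668 to 3777). The 2 phz operons are near-identical. All their measured probe sets, these 4 and that of phzC2 included, carry the suffix for shared probes, so the signals cannot be assigned to a single operon. The list was fixed with 17 genes, and those not measured belong to these operons. Of the genes without a second copy, phzS had a ratio of 1.85, phzM 1.19 and phzH 0.722. The core-enzyme probe set phzC2 had a ratio of 1.09. The gene phzC2 was chosen after its value was seen. The genes phzS, phzM and phzH lie outside the naming rule too. A test given below was set on them before their values were seen.

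Quorum-controlled exoproducts were also higher as a group. The 15 secreted virulence genes had a median log2 ratio of 0.38 (percentile 99.97), with 11 above 0, 3 below 0 and 1 past 2-fold: cbpD, the chitin-binding protein gene, at 2.76-fold (558 to 1538). The elastase gene lasB was at 1.73-fold, the protease gene lasA at 1.67-fold and the cyanide synthase gene hcnA at 1.64-fold, whereas the chitinase gene chiC was at 0.726. The alkyl quinolone (PQS) list had a median log2 ratio of 0.17 (percentile 94.8), with pqsA at 1.71-fold, pqsD at 1.47-fold, phnA at 1.44-fold and pqsC at 1.25-fold. The las and rhl list, which also holds the rhamnolipid synthesis genes rhlA, rhlB and rhlC, had a median of 0.02 (percentile 72.7), with rhlB at 1.86-fold, rhlA at 1.30-fold, rhlR at 1.22-fold, lasR at 1.13-fold and the signal synthase gene lasI at 0.707. The genes chiC and lasI were chosen after their values were seen.

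The strongest single difference was in glycerol use. The glycerol-3-phosphate dehydrogenase gene glpD was 6.84-fold higher (522 to 3567), the glycerol channel gene glpF 5.51-fold higher (397 to 2188), the glycerol kinase gene glpK 4.92-fold higher (370 to 1819) and the repressor gene glpR 2.12-fold higher (502 to 1063). In the same list of 25 sugar and glycerol genes, PA3187, PA3188 and PA3189 of the glucose uptake group were 2.19-fold, 2.62-fold and 3.19-fold lower, and PA3190 was 1.84-fold lower. The glucose porin gene oprB, next to them, had a log2 ratio of -0.29 and was chosen after its value was seen. Its probe set carries the suffix for shared probes, so the signal may include other sequences. With 4 genes past 2-fold upward and 3 downward, the list median was 0.00 (percentile 59.8).

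The other genes with the lowest ratios belonged to no single list. PA1913 was 3.16-fold lower (1342 to 425). PA5352 was 2.71-fold lower and glcD, a glycolate oxidase subunit gene, 2.09-fold lower (756 to 361). The gene dgcB, of dimethylglycine breakdown, was 2.55-fold lower with its supernatant signal at the floor, recR, of DNA repair, was 2.27-fold lower and ccmG, of cytochrome c maturation, 2.14-fold lower. PA3500, PA2263, PA2795, PA1702, PA5020 and PA4826 were between 2.08-fold (PA4826 and PA5020) and 2.28-fold (PA3500) lower. Each of these has its brighter signal between 291 (PA1702) and 424 (PA2795). PA4826 and PA1702 were short of 2-fold under quantile and loess scaling, PA5020 under loess, and these 3 with dgcB, recR and PA2263 with a floor at the 40th percentile.

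With the floor, no measured gene of the fixed lists for the biofilm matrix or attachment was past 2-fold in either direction. Without it pelE was lower by more than 2-fold (177 on the control array), and algD (86.6 to 41.6), algL (35.0 to 71.2) and cupB3 (9.90 to 27.8) were past 2-fold, these 3 with both signals under the floor and chosen after their values were seen. The pel list, for a matrix polysaccharide, had a median log2 ratio of -0.22 (percentile 12.3), with pelE at -0.72, pelF at -0.67, pelB at -0.45 and pelG at -0.22; pelE and pelB reached the floor with the supernatant. The psl list had a median of 0.08 (percentile 87.3), with pslI at 0.75, pslB at 0.40, pslD at 0.31 and pslC at 0.25. Alginate genes had a median of 0.00 (percentile 51.4), with 7 of 12 at the floor on both arrays and alg44 lowest at -0.64. The cup fimbriae also had a median of 0.00 (percentile 55.3), with cupA3 at -0.58 and cupA4 at -0.51. Type IV pili genes, used for twitching and attachment, had a median of -0.09 (percentile 24.3), with pilO at -0.64 and pilA, the pilin gene, at -0.38. The 45 flagellar genes had a median of -0.05 (percentile 28.9), 21 above 0 and 24 below. The cyclic di-GMP list, which covers the second messenger of biofilm formation, had a median of 0.16 (percentile 99.5). Of its 21 genes 12 were above 0, led by wspD at 1.82-fold and yfiR at 1.60-fold. The 8 below 0 included wspR at -0.37, chosen after its value was seen. By its mean the list was at percentile 93.5, and by its median with a floor at the 40th percentile at 52.4. The ratios do not measure the messenger itself.

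**Figure D3:**
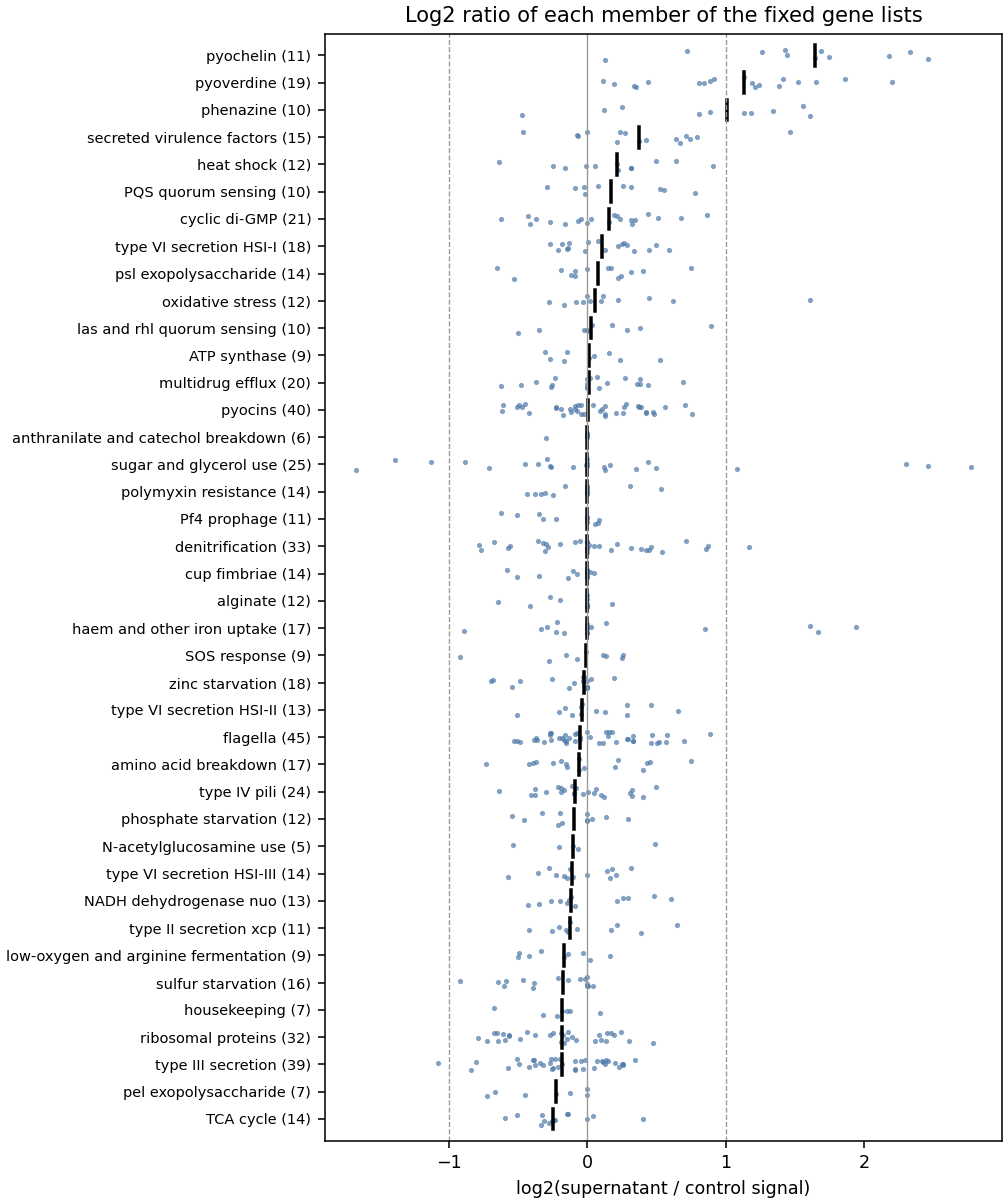
Log2 ratio of supernatant over control signal (x) for each measured member (points, with vertical scatter for visibility) of the 40 fixed gene lists (y, number of members in brackets); black bars are list medians and dashed lines mark a 2-fold difference. The pyochelin, pyoverdine and phenazine medians are 1.64, 1.13 and 1.01, and the next is 0.38 for secreted virulence factors.

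Type III secretion genes, which build the needle that injects toxins into host cells, had a median log2 ratio of -0.19 over 39 genes, 26 of them below 0, at percentile 0.55. The lowest were PA1702 at -1.08, pcrR at -0.84, pscR at -0.81 and pscO at -0.57. Quantile and loess scaling moved the list to percentiles 5.68 and 4.11, and a floor at the 40th percentile moved it to 3.62. The type VI clusters had medians of 0.10 (HSI-I, percentile 91.6), -0.04 (HSI-II, percentile 54.6) and -0.11 (HSI-III, percentile 14.4), and the xcp type II machine -0.12 (percentile 20.8). PA0089 of the HSI-I cluster was at 0.59, PA1666 of HSI-II at -0.51, PA2369 of HSI-III at -0.57 and xcpU at -0.42.

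Which stress group passed the upper percentile bound depended on the summary. The heat shock list had a median log2 ratio of 0.22 (percentile 98.8), but its mean was at percentile 97.15, short of the bound. Of 12 genes 8 were above 0, 4 below and none past 2-fold, with the co-chaperone gene dnaJ at 1.88-fold, hslU at 1.56-fold, ibpA at 1.41-fold and lon at 1.25-fold; groES, the brightest gene on both arrays, was at -0.64, groEL at -0.25 and grpE at -0.16, all 3 chosen after their values were seen. Of 12 oxidative stress genes only sodM passed 2-fold (median 0.06, percentile 92.4, and mean at percentile 99.07), and oxyR was at 1.53-fold. The gene sodM is also in the list of other iron uptake genes, and its control signal was at the floor. The SOS list, for DNA damage, had a median of -0.01 (percentile 53.0), the 40 pyocin genes 0.01 (percentile 70.2) and the Pf4 prophage 0.00 (percentile 70.7). Multidrug efflux genes had a median of 0.01 (percentile 88.5), with mexH at 1.61-fold, mexG at 1.36-fold and mexI at 1.30-fold, and polymyxin resistance genes had 0.00 (percentile 57.3).

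Nutrient groups other than iron had medians at or below 0. The sulfur starvation list was at -0.18 (percentile 3.62), with the sulfate-binding protein gene sbp at -0.92, PA3442 at -0.64 and cysA at -0.59, and it was at percentile 0.35 without a floor but at 50.56, with a median of 0.00, with a floor at the 40th percentile. Zinc starvation genes were at -0.03 (percentile 6.01), with PA4837 at -0.69 and PA5535 at -0.68, and phosphate starvation genes at -0.09 (percentile 17.6), with phoA at -0.55. Amino acid breakdown had a median of -0.06 (percentile 46.5), with liuA at -0.73. N-acetylglucosamine use was at -0.11 (percentile 52.8), and anthranilate and catechol breakdown at 0.00 (percentile 52.3) with 5 of 6 genes at the floor.

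Gene lists of energy metabolism and translation were close to equal or slightly lower by their medians. The TCA cycle list had a median log2 ratio of -0.25 (percentile 2.29), with lpdG at -0.60, sucA at -0.51, sucC at -0.33 and idh at -0.33; under quantile and loess scaling it was at percentiles 12.5 and 11.8. The 32 ribosomal protein genes had a median of -0.18 (percentile 5.12), with rpsN at -0.79, rplB at -0.73, rplW at -0.67 and rplP at -0.65, and under quantile and loess scaling the median turned to 0.01 and 0.05. ATP synthase genes were at 0.02 (percentile 66.1) and NADH dehydrogenase genes at -0.12 (percentile 24.0). Low-oxygen and arginine fermentation genes were at -0.17 (percentile 22.7), with ccoP2 at -0.50 and arcB at -0.50. Of 33 denitrification genes (median 0.00, percentile 62.8), 15 were above 0 and 13 below. Only napF passed 2-fold, at 2.25-fold, and its log2 ratio was 0.46 with a floor at the 40th percentile. The gene nosR was at -0.78, while nirS was at 1.83-fold and nirL at 1.81-fold, both chosen after their values were seen.

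The 7 measured housekeeping genes had a median log2 ratio of -0.18 (percentile 19.7), with rpoD, the main sigma factor gene, at 0.09 (4181 to 4462). The others were gyrB at -0.13 (2038 to 1866), ftsZ at -0.15 (5335 to 4808), gyrA at -0.18 (1713 to 1512), proC at -0.22 (1467 to 1259), rpoC at -0.32 (8322 to 6671) and rpoB at -0.67 (3808 to 2386). The brightest genes were lower on the supernatant array. The median log2 ratio was -0.50 for the 20 brightest genes by mean signal, 19 of them below 0, -0.28 for those ranked 21 to 50 and -0.11 for those ranked 51 to 100. The ribosomal protein genes with the lowest ratios are among the brightest.

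Genes next to each other on the chromosome had similar ratios. The log2 ratios of 5438 pairs of genes with consecutive locus tags correlated with Pearson's r = 0.22 and Spearman's rho = 0.12 across genes, and 1000 shuffles of the gene order gave values of r between -0.06 and 0.04. Over the 2071 pairs in which the brighter signal of both genes was at or above the median, r was 0.33. Without any gene of the fixed lists, r was 0.11 over 4641 pairs.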

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

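The values in this part come from probe sets outside the comparison of genes, picked by a threshold set after the data were seen: a supernatant signal at least 2-fold that of the control and a brighter signal at or above the gene median. The rule looks only for signals above the control, so probe sets that were lower, such as that of PA5086 (771 to 250, log2 ratio -1.63), are not picked by it. The probe set for glycine tRNA had a log2 ratio of 1.23 (560 on the control array, 1315 on the supernatant array). It carries the suffix for shared probes. The probe sets of other tRNAs had log2 ratios from -0.88 (leucine) to 0.80 (lysine). The probe set with the locus tag PA2731, which had no match in the annotation used here, had a log2 ratio of 1.04 (771 to 1591). Neither has a replicate, and groups of 1 array allow no check for samples far from the others or for effects that differ between groups.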

How the results depend on the processing

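No paired analysis was possible because each group is 1 array, and for the same reason no array could be left out. Counts of genes depended on the floor and the threshold, which set them by construction. Against 53 higher and 23 lower genes, there were 155 and 129 without a floor, 40 and 12 with a floor at the 40th percentile, 241 and 253 at a threshold of 1.5-fold, and 17 and 2 at 3-fold. The 3 other scalings gave 57 to 64 higher and 16 to 18 lower genes and kept all 53 higher genes, and 40 higher and 9 lower genes passed 2-fold under every scaling and floor. The number of lists at or above the upper percentile bound was 6, and 5 to 8 under the alternatives, but the members differed. With list means heat shock (percentile 97.15) and cyclic di-GMP (93.45) dropped out, and other iron uptake (99.96) and oxidative stress (99.07) came in. These last lists share the gene sodM. The number at or below the lower bound was 2 (type III secretion and the TCA cycle), but 0 under quantile normalization, 0 after loess, 1 with a floor at the 40th percentile (type III secretion dropped out at percentile 3.62), 4 with list means and 3 without a floor. With list means the TCA cycle dropped out (percentile 2.95), and the 4 were type III secretion (0.32), ribosomal proteins (0.09), sulfur starvation (0.24) and zinc starvation (1.77). The cause of the losses under other scalings was not tested. The correlation of neighbouring genes was 0.13 without a floor and 0.33 for brighter pairs. No list or named gene that passed its threshold changed direction under another scaling or floor. Of the 210 named genes, 16 dropped under 2-fold with the higher floor, namely napF, recR, PA1702, PA2263, PA2393, PA2411, PA2427, PA3577, PA3579, PA4219, sodM, PA4772, PA4826, PA5020, PA5136 and dgcB. Of these, PA2427, PA4772 and PA5136 were chosen after their values were seen. They were 2.26-fold, 2.27-fold and 2.96-fold higher in the main setting, with control signals at the floor. Signals near the floor, without detection calls, limit what can be said of pel, alginate and cup genes.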

Other observations

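Runs of neighbouring genes extended beyond the lists. There were 10 runs of at least 3 consecutive loci with log2 ratios of at least 0.8 in size, 9 higher and 1 lower, holding 46 genes, against at most 2 runs in 1000 shuffles of gene order. PA4218, PA4219 and PA4220, between phzS and the pyochelin receptor gene fptA, were 2.54-fold, 2.52-fold and 1.95-fold higher. PA3579 and PA3580, before glpF, were 2.75-fold and 2.67-fold higher, and PA3575 and PA3577 2.67-fold and 2.35-fold. The glycolate oxidase region formed no such run and was not tested as a set. Beside the named glcD and PA5352, glcE was at a log2 ratio of -0.99 and rubA1 at -0.86. The gene glcF was at -0.50 with its supernatant signal at the floor, and glcB, for malate synthase, was at 0.81. All genes with a ratio given in this paragraph were chosen after their values were seen.

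Of the tests below, those of dim probe sets, of sugar uptake and of the brightest probe sets were chosen only after the result was seen. The other tests were written before the values they measure were seen.

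The higher siderophore and iron uptake genes were weighed first. A trend of the ratio with signal is argued against, since the 30 pyoverdine and pyochelin genes had a median log2 ratio of 1.25 as deposited and 1.29 after loess. The 30 of the 47 measured genes of the 3 iron lists whose brighter signal was at or above the gene median had a median of 1.42, but a higher supernatant signal itself lets a gene pass that filter, so this decides nothing on noise of dim probe sets. A filter on the control signal works against a higher ratio, and the 15 genes that pass it also had a median of 1.42. That value rests on pyochelin, with a median of 1.64 over 9 genes, while the 5 pyoverdine genes that pass had 0.44, under the bound set against noise, and tonB1 had -0.22. The pyochelin and pyoverdine lists, with all 11 and all 19 genes above 0, were at percentile 100 of matched random lists under every scaling and floor. Both percentiles were known when the bound for them was set, so they lend no separate support. The matching also used the mean signal of both arrays, which includes the higher supernatant signal. Random lists may thus carry less noise than genes dim on the control array. For pyochelin, noise of dim probe sets is argued against by the 9 genes that pass the filter on the control signal. For pyoverdine, noise that is independent from gene to gene is argued against only as the source of the common direction, since all 19 genes were above 0. Some of these had a control signal at the floor. The size of the pyoverdine rise stays open, since the list median fell from 1.13 to 0.81 with a floor at the 40th percentile. Noise also stays open for the other iron uptake genes, whose median was at percentile 63.0. A lower iron supply stays open. A set of 10 genes that low iron is known to repress through the PrrF small RNAs had a median log2 ratio of -0.15. This was at percentile 19.8 of matched random lists, between the bounds set for either outcome. Among them sdhA, sodB and the iron storage gene bfrB were at -0.31, -0.28 and -0.10. The genes acnA and PA4880 went the other way, at 0.40 and 0.70, and the rest were below 0. With 1 array per group a chance difference between 2 cultures, for example in growth stage, stays open too.

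The higher phenazine signals leave more open. Cross-hybridisation between the phz operon copies could hide which copy differed, and the 3 genes without a copy had a median log2 ratio of 0.25, which does not decide. Higher acyl-homoserine lactone signalling was tested on the las and rhl list, at percentile 72.7, and higher alkyl quinolone signalling on the PQS list, at percentile 94.8. Neither list reached the bound set for its explanation or the bound set against it, so both remain possible.

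The lower ratios of the brightest probe sets were weighed between 2 explanations, and both stay open. On the control array the probe sets for 23S rRNA, 16S rRNA and the strand of rnpB, the RNase P RNA, were at 44652, 41257 and 38953, and on the supernatant array at 21400, 20143 and 19269, log2 ratios of -1.06, -1.03 and -1.02. The median log2 ratio of the 20 brightest genes was -0.50, against 0.05 in the 9th decile of signal. These values restate the pattern, so they lend no support to detector saturation on arrays scaled by different factors, which stays open without scanner values. A lower share of the translation machinery stays open too, since its test depends on the setting. The ribosomal protein list was at percentile 5.12 by its median as deposited, between the bounds set for either outcome. It was at 0.09 by its mean, and at 73.5 and 78.3 under quantile and loess scaling, which level the 2 arrays at the bright end.

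A hypothesis for the glycerol genes is that the supernatant brought glycerol or a compound that yields glycerol-3-phosphate, which relieves repression by GlpR; the composition of the Streptomyces medium is not given in the sources used here. Noise of dim probe sets is argued against by the control signals of the 4 glp genes, from 370 (glpK) to 522 (glpD), against a gene median of 268. These signals were known when the bound was set. A chance difference between the cultures stays open for these genes too. Their smallest brighter signal of 1063 decides nothing, since it is a supernatant signal (glpR). The other 21 genes of the sugar list had a median log2 ratio of -0.10, so as a group they did not share the rise. The ratios of the list were known when this test was chosen. Its outcome was fixed, and it lends no separate support against a general rise of sugar uptake. The hypothesis itself was not tested, and nothing in these arrays measures the medium. It would be tested by measuring glycerol in the supernatant and glp transcripts in biofilms given unused Streptomyces medium, or glycerol alone, in place of the supernatant.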
